A study of Bos taurus with 40 samples.

How the data were processed

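The table holds raw counts of reads per gene, made by the authors with featureCounts after alignment to the bovine genome build UMD3.1 with HISAT2 and quality checks with FastQC, per the submitters' processing notes, which give no versions in the sources used here. Per the labels' protocols, total RNA came from homogenised endometrium, was treated with DNase on a column and went into stranded, poly(A)-based mRNA libraries of Illumina. The deposited counts are whole numbers and were used as they stand. The table holds 32671 named genes and 1 mitochondrial genome row, which was kept out of library sizes and tests. Its share ranged by day from a mean of 0.119% to 0.424%. No reads fell on 3987 of the genes, 27 gene names had turned into dates, and these names were not used. Of the gene names, 20070 are symbols in the reference table of bovine genes and another 657 are synonyms there. Genes with near-identical copies and second entries of a name are uncertain, since the handling of shared reads is not given in the sources used here. No genome of that build was used here.

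Samples were grouped by the day and the horn in their labels (8 groups of 5), and the number in each title was taken as the tag of the heifer, which the design text implies for 2 horns of each heifer. The tags were checked as pairs through the correlation, across genes, of deviations from the group means. The 2 libraries of a tag correlated above 0.1 in 5 of 20 tags (range -0.258 to 0.669, median -0.0464), so the p-values of fits with this block, sums over a tag and counts of tags with 1 sign rest on the labels. Each ipsilateral library and its best match in the other horn, whatever its tag, correlated at 0.138 to 0.734 (median 0.486). No fit on these matched pairs was run. The rule for on/off genes used in a second check was changed after results were seen, and all 4 versions tried, with 13 to 23 genes, gave 5 own-tag matches, while 15 to 20 libraries were equal to their best match at all genes. Library totals ranged from 27.03 to 64.4 M. No column repeats another (0 identical columns), and replicates in a group were treated as separate animals.

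The tests were edgeR 4.0.16 quasi-likelihood tests on counts scaled with TMM factors and filtered with filterByExpr, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The horn comparisons used all 40 libraries with 20 tag terms and 1 ipsilateral minus contralateral term per day, on 20356 genes; the average over days and the change of the difference with day (interaction) are contrasts of that fit. The day comparisons summed the counts of the 2 horns per tag, giving 20 sums and 20995 genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a comparison; fry asks whether members move one way on balance and not whether they differ from other genes. There were 30 lists, 14 of pathways and 16 of cell types, with 576 of 589 entries in the table, and 29 had at least 3 tested members. Counts per list are given over all genes and adjusted over the list alone. Values are CPM or log2 fold changes with standard errors. Measures of single libraries were compared between horns with exact two-sided permutation tests of 252 arrangements.

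The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule takes, for each horn comparison, genes that passed at an average log2 CPM of at least 0 with the same sign in at least 4 of 5 tags (16 of 20 for the average), the 10 highest and 10 lowest log2 fold changes. For each day comparison, genes that passed at an average log2 CPM of at least 2 with no overlap between the days, the 8 highest and 8 lowest. It adds up to 4 members of each list in each comparison; and always PGR, ESR1, OXTR, ISG15 and MX1. It named 530 pairs of gene and comparison (350 genes), of which 245 (173 genes) stand in the text, picked among the genes of the rule after their values were seen. Some genes that the rule names are not reported here.

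The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, a robust prior, no tag block, the libraries of 1 day or 1 horn, only the 10 heifers of the 2 days, and each tag left out in turn. Chosen after seeing the data were the log2 share of reads in the 801 microRNA and 1594 tRNA genes as a covariate, log2 depth as a covariate, the libraries of 1 day with no tag block, fits without ipsilateral library 5-137, and list tests with each covariate and in single horns. The edgeR horn and day fits, camera and the pairing check were tested on simulated data with known answers, for the horn difference of day 5 (20127 genes) and for days 7 to 13 (20314 genes). In the first, 23.9% of the genes changed 1.5-fold were found, 49.3% of those changed 2-fold and 74.2% of those changed 4-fold, with 3 unchanged genes among 101 called. In the second these shares were 47.8%, 62.7% and 92.4%, with 9 unchanged genes among 144. In the same simulations the unchanged comparisons, the horn difference of day 7 and days 13 to 16, had 0 edgeR calls. Apart from the changed genes, these simulated counts had 1 mean level per gene and no differences between animals. The genes changed 1.5-, 2- and 4-fold numbered 67, 67 and 66, far fewer than passed in the real comparisons. The shares found and the 0 calls therefore do not give the power or error of the real fits. R 4.3.3, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.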

Results

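The series set the endometrium, the inner lining of the uterus, of one uterine horn against that of the other. The ipsilateral horn lies on the side of the corpus luteum, the gland that forms from the ovulated follicle and secretes progesterone, and the contralateral horn lies on the other side. Both horns were sampled from 20 heifers, 5 on each of days 5, 7, 13 and 16, which gave 40 RNA-seq libraries in 8 groups of 5. The labels count the days as days of pregnancy and the design text as days after estrus, and whether embryos were present is not given in the sources used here. Reads assigned to genes ranged from 27.03 to 64.4 M per library, and the second deepest library held 41.3 M. Mean depth on day 5 was 38.9 ± 15.2 M (SD, n = 5) in the ipsilateral and 35.4 ± 2.60 M in the contralateral horn. The question of the series was whether the horns differ in gene expression, and the days allow the same tissue to be followed through the luteal phase.

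Day was the main axis of the data. The first principal component took 42.1% of the variance over the 2000 most variable genes and placed the libraries of days 5 and 7 apart from those of days 13 and 16, and the second took 11.9%. The exception was the ipsilateral day 16 library 5-137, at 6.91 on the first component, where the other 4 ipsilateral day 16 libraries lay between 50.3 and 56.8.

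**Figure D1:**
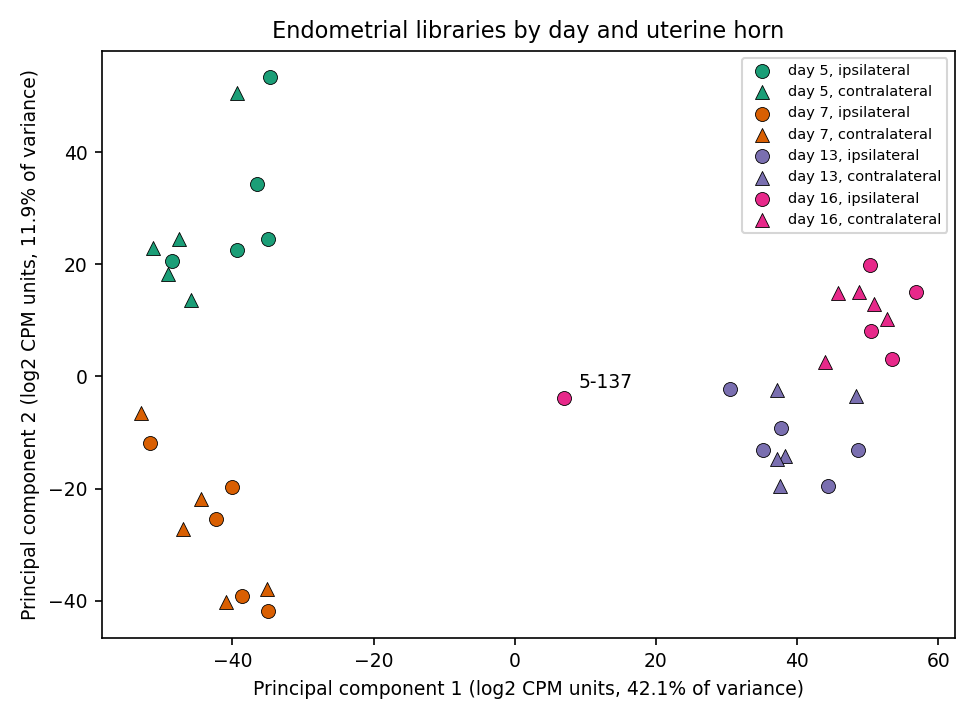
Each point is 1 library, placed by its scores on principal components 1 and 2 (log2 CPM units), with the day as colour and the horn as shape. Days 5 and 7 lie on the left and days 13 and 16 on the right, except ipsilateral day 16 library 5-137, at 6.91 on component 1.

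The animal tags in the sample names did not pair the libraries of the 2 horns at genes that vary between animals. At 13 genes that were either clearly expressed or nearly silent in a library, chosen by a rule set after the data were seen, each ipsilateral library had the states of 1 contralateral library of its day at 100% of the genes, and that library carried the same tag in 5 of 20 cases. The horn comparisons kept the tag as a block, as the design had it, and counts of tags given for the horns pair libraries by label and are not counts of animals. The standard errors, p-values and gene counts between horns rest on these labels too. They are not those of a comparison within animals, and no fit on the matched pairs was run. The day comparisons summed the 2 horns by tag. Where a tag joins libraries of 2 heifers, its sum mixes them and each heifer enters 2 sums. Leaving out such a tag does not leave out a heifer, between horns or between days, since both heifers stay in through other tags. The 5 sums of a day are then not independent, and the SD, standard errors and p-values between days may be too small.

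**Figure D2:**
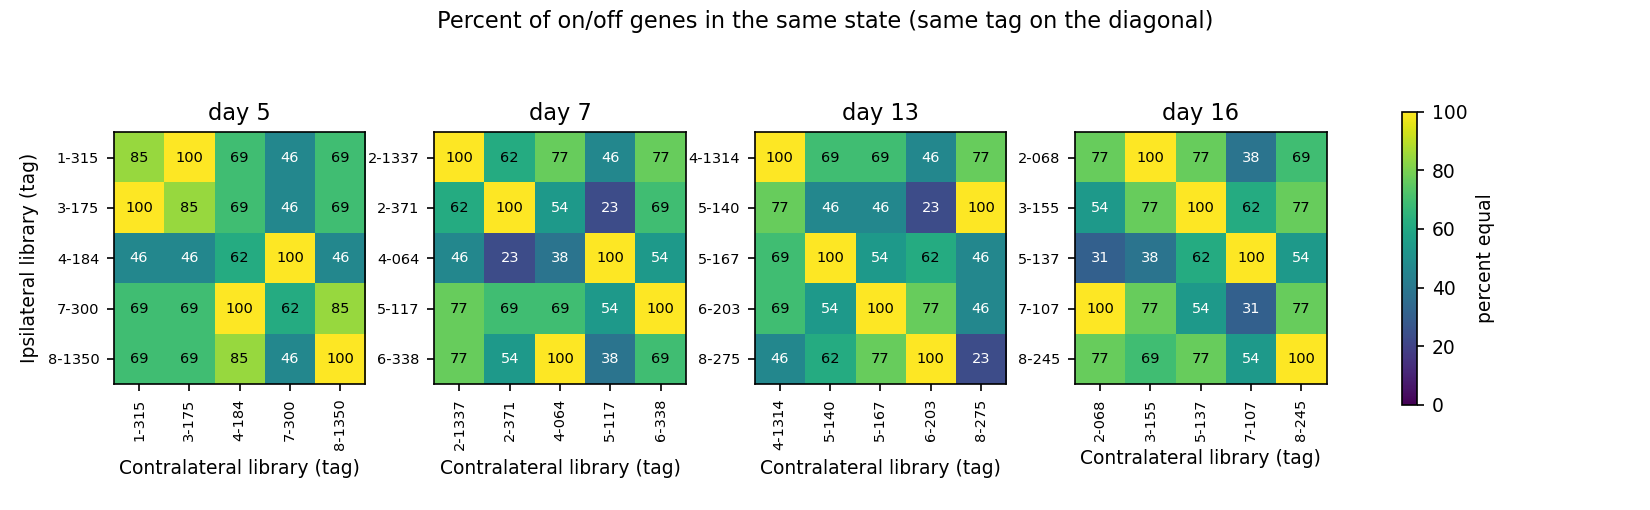
Each square gives the percent of the 13 on/off genes in the same state in an ipsilateral library (vertical axis, by tag) and a contralateral library (horizontal axis, by tag) of the same day. The squares at 100% lie off the diagonal of equal tags in 15 of 20 cases.

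Averaged over the 4 days, the ipsilateral horn had higher levels of the signalling regulator NF1 (log2 fold change 1.67 ± 0.34 SE, 3.17-fold, adjusted p = 0.000643), of SLFN12 (1.66 ± 0.28), of the microtubule protein gene DCX (1.46 ± 0.26) and of SCAI (1.37 ± 0.18). The centrosome gene CEP162 (1.26 ± 0.13) and the WNT co-receptor LRP6 (0.64 ± 0.05) were higher in 20 of 20 tags. Also higher were LNPEP (1.23), KCNA2 (1.55), PAK3 (1.44) and NR3C1, the glucocorticoid receptor (0.47, in 19 of 20 tags). Lower in the ipsilateral horn were GPRIN1 (-0.88 ± 0.14), the surface mucin MUC1 (-0.59 ± 0.09, in 19 of 20 tags), the collagen gene COL1A1 (-0.59), the matrix genes TNXB (-0.56) and ITGA11 (-0.54), GPC3 (-0.64), POU3F4 (-0.77) and the keratin KRT8 (-0.42, in 20 of 20 tags). Progesterone and estrogen receptors did not pass, with PGR at 0.16 ± 0.12 (adjusted p = 0.304) and ESR1 at -0.16 ± 0.09 (adjusted p = 0.174). Neither did OXTR (-0.06 ± 0.32), ISG15 (-0.23 ± 0.70) or MX1 (-0.23 ± 0.53).

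Among the lists fixed beforehand, members of the epithelium list were lower in the ipsilateral horn on average, 13 of 18 (14 adjusted over the list alone) and none higher, with a median of -0.35 (adjusted p = 2.15e-05, and 0.988 with an estimated correlation). Of the secreted components of uterine fluid, 10 of 29 were lower (10 adjusted over the list alone; adjusted p = 0.00685). Of the cholesterol synthesis and uptake list, 12 of 23 were lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.00685). Of the extracellular matrix list, 15 of 36 were lower and 2 higher (16 and 2 adjusted over the list alone; adjusted p = 0.0108). Each of these 3 stood at adjusted p = 0.988 with an estimated correlation. No list passed at an estimated correlation, and 64 to 98 of 100 splits of the same samples called as many lists as the real groups in the horn comparisons, although these splits, unlike the real groups, could put 2 libraries that matched at the on/off genes on the same side. Such splits could also keep part of the real horn difference, so their counts of lists neither exclude chance nor point to it.

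In total 7570 of 20356 genes passed (edgeR quasi-likelihood, adjusted p below 0.05), 3812 higher and 3758 lower, and 222 of them differed by 2-fold or more, 221 higher. The median absolute log2 difference of these genes was 0.29. Reads in microRNA genes were more frequent in the ipsilateral libraries by 1.29, 1.31 and 1.27 times on days 5, 7 and 13 (exact permutation p = 0.00794, the smallest possible, and 0.0423 adjusted over 16 tests, two-sided) and by 1.18 times on day 16 (exact p = 0.0635, adjusted 0.141). Reads in tRNA genes were at 1.16 to 1.18 times on the 4 days and did not pass (adjusted p = 0.106, 0.162, 0.141 and 0.0635). With the log2 share of microRNA and tRNA reads as a covariate, a choice made after the data were seen, 283 genes passed, 194 higher and 89 lower. The median log2 difference in the original direction of the 7570 genes went from 0.29 to 0.20 while their median standard error went from 0.06 to 0.13. In that fit the secreted-components and extracellular matrix lists did not pass (adjusted p = 0.691 and 0.578), the median of the first turned to 0.05 and TNXB turned to 0.10. With log2 depth as a covariate instead, also a later choice, 7392 genes passed, and the extracellular matrix list did not (adjusted p = 0.0516).

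**Figure D3:**
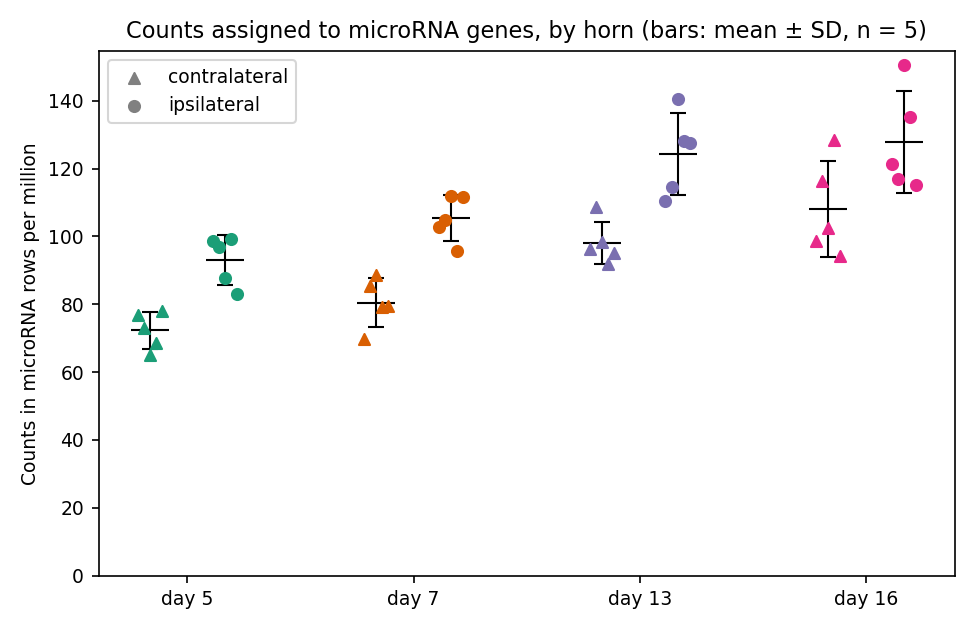
Reads assigned to microRNA genes as CPM (vertical axis) by day and horn, with 1 point per library and bars for the mean ± SD of 5. The ipsilateral mean was above the contralateral one on each day, from 93.0 against 72.3 on day 5 to 128 against 108 on day 16.

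On day 5, the ipsilateral horn had more of the muscarinic acetylcholine receptor CHRM2 (log2 fold change 2.66 ± 0.83; 123 ± 60.2 against 23.4 ± 19.8 CPM, SD, n = 5), the cholecystokinin receptor CCKAR (3.96 ± 1.34; 5.88 ± 7.03 against 0.306 ± 0.434 CPM), NF1 (3.13 ± 0.67), SCAI (2.43 ± 0.37), DCX (2.42 ± 0.51), and CCDC73 (2.30), each in 5 of 5 tags. IGFBP1, whose product binds insulin-like growth factors, was nearly silent on this day, at 0.488 ± 0.545 against 0.0578 ± 0.0812 CPM, and its call was lost without each of the 5 tags in turn. LRP6 (1.05 ± 0.11) and NR3C1 (0.61 ± 0.11) were higher as well. Lower in the ipsilateral horn were MUC1 (-0.96 ± 0.18; 50.4 ± 15.5 against 96.5 ± 22.1 CPM), GPRIN1 (-1.32 ± 0.30), ASGR1 (-1.28; 0.195 ± 0.0886 against 0.476 ± 0.143 CPM), TCTE1 (-1.12), FAM124A (-1.04), TUBB4A (-0.97), the myosin MYH14 (-0.88), the choline transporter SLC44A4 (-0.87), the replication gene MCM5 (-0.65) and COL1A1 (-0.70).

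On the same day, 12 of the 18 epithelium markers were lower and none higher (15 adjusted over the list alone; adjusted p = 4.13e-09, and 0.251 with an estimated correlation). Among them were KRT8 (-0.77 ± 0.12), the membrane protease ST14 (-0.68 ± 0.10) and its inhibitor SPINT1 (-0.60 ± 0.10). Of 16 smooth muscle markers 2 were higher and none lower (1 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.316 for the set), and with no tag block 5 were higher and none lower (7 and 0 adjusted over the list alone; median 0.84, adjusted p = 0.249). Of the cholesterol list, 8 of 23 were lower and 1 higher (10 and 1 adjusted over the list alone; adjusted p = 0.00221, and 0.971 with an estimated correlation). They included EBP (-0.77) and DHCR7 (-0.62), enzymes of late sterol synthesis, and SREBF2 (-0.55), which drives the pathway. PGR (0.19 ± 0.23), ESR1 (-0.07 ± 0.18), OXTR (0.17 ± 0.61) and the interferon-stimulated genes ISG15 (-0.24 ± 1.69) and MX1 (-0.29 ± 1.25) did not pass. Across all genes 4220 passed, 2209 higher and 2011 lower. From the day 5 libraries alone 1760 passed with the tag block (1414 higher, 346 lower) and 2884 without it (2012 higher, 872 lower), and with the background covariate 600 passed. Of the 25 named genes that passed, 17 kept the call without each tag in turn, and the other 8 (CCKAR, IGFBP1, CHRM2, ASGR1, TCTE1, FAM124A, TUBB4A and COL1A1) lost it without at least 1 tag. Their adjusted p reached up to 0.209 (IGFBP1 without tag 3-175). With log2 depth as a covariate, IGFBP1 (adjusted p = 0.147) and TCTE1 (adjusted p = 0.0607) did not pass, nor did they with no tag block (adjusted p = 0.0571 and 0.0526).

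On day 7, SLFN12 (2.31 ± 0.58), DCX (2.05 ± 0.52), FAM199X (1.74), UHMK1 (1.70), LRRC58 (1.57 ± 0.29), the amino acid transporter SLC38A1 (1.52 ± 0.43), NR3C1 (0.66 ± 0.11) and LRP6 (0.60 ± 0.10) were higher in the ipsilateral horn. Lower were the collagen receptor subunit ITGA11 (-0.74 ± 0.20), the extracellular superoxide dismutase SOD3 (-0.64), HSPB6 (-0.58), CHPF (-0.56 ± 0.11), the matrix protein FBLN1 (-0.53) and EEF1G (-0.51). The protein folding genes PDIA4 (-0.44 ± 0.10), PDIA6 (-0.37 ± 0.08) and HSP90AB1 (-0.34) and the protease CTSB (-0.42) were lower too. In the heat shock and unfolded protein response list, 5 of 26 members were lower and none higher (6 adjusted over the list alone; adjusted p = 0.026). Secreted components, the extracellular matrix and epithelium lists were lower as sets (adjusted p = 0.0121 for each), although 1 of 29, 1 of 36 and 0 of 18 members were lower and 1 extracellular matrix gene was higher (0 in either direction adjusted over the list alone). With an estimated correlation, each of these 4 lists was at adjusted p = 0.974, and with the background covariate the secreted-components list, whose median turned to 0.14, and the extracellular matrix list did not pass (adjusted p = 0.527 and 0.419). PGR (0.22 ± 0.23), ESR1 (-0.04 ± 0.18), OXTR (0.07 ± 0.64), ISG15 (-0.83 ± 1.51) and MX1 (-0.43 ± 1.11) did not pass.

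In total 2054 genes passed on day 7, 1378 higher (67.1%) and 676 lower, and 54.6% of the genes called by DESeq2 were higher. Without tag 2-1337, 4-064 or 5-117 the count was 839, 1260 or 853, with 663 higher in the first and 681 in the last. From the libraries of this day alone it was 619 with the tag block (567 higher, 52 lower) and 1624 without it, and with the background covariate edgeR called 0 genes (1673 at unadjusted p below 0.05). Of the 18 named genes that passed, LRRC58, CHPF, NR3C1, LRP6, PDIA4 and PDIA6 kept the call without each tag in turn, and the other 12 lost it without tag 2-1337, among other tags, with adjusted p of up to 0.241 (FBLN1 without tag 5-117). FBLN1 did not pass with log2 depth as a covariate either (adjusted p = 0.0536), and with no tag block ITGA11 and HSP90AB1 did not (adjusted p = 0.0544 and 0.0722).

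On day 13, the ipsilateral horn had higher levels of CEP162 (1.21 ± 0.26), CEP290 (1.02 ± 0.15), CEP135 (0.97), KIF20B (1.08), SMC4 (1.00), PPIG (1.07 ± 0.15), GCFC2 (1.02 ± 0.18) and LRP6 (0.48 ± 0.10). It had lower levels of FAM53B (-0.55 ± 0.13), PCDH1 (-0.51), CHPF (-0.47), TOB2 (-0.46), BCR (-0.45), SLC9A3R1 (-0.43), SREBF2 (-0.42) and SPINT1 (-0.37). As sets, epithelium (adjusted p = 0.000127, 1 of 18 members lower), secreted components (adjusted p = 0.000351, 0 of 29), cholesterol synthesis and uptake (adjusted p = 0.000351, 1 of 23), extracellular matrix (adjusted p = 0.00745, 0 of 36) and macrophages and dendritic cells (adjusted p = 0.0299, and 0.0562 with no tag block, 0 of 17) were lower. In that order, 1, 0, 1, 0 and 0 members passed adjusted over the list alone. With an estimated correlation each of the 5 stood at adjusted p = 0.7645, and with the background covariate the secreted-components list, whose median turned to 0.06, the extracellular matrix list and the macrophage list did not pass (adjusted p = 0.974, 0.551 and 0.373). PGR (0.15 ± 0.24), ESR1 (-0.27 ± 0.18), OXTR (-0.08 ± 0.70), ISG15 (-0.06 ± 1.22) and MX1 (-0.15 ± 0.98) did not pass.

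In total 890 genes passed on day 13, 731 higher (82.1%) and 159 lower, and DESeq2 called 1720, of which 58.5% were higher. Without tag 4-1314, 5-167, 6-203 or 8-275 the count was 396, 554, 349 or 369, with 366 higher in the first and 341 in the last. From the libraries of this day alone it was 388 with the tag block (366 higher, 22 lower) and 742 without it, and with the background covariate edgeR called 0 genes (1290 at unadjusted p below 0.05). Of the 16 named genes that passed, PPIG, CEP290, GCFC2 and PCDH1 kept the call without each tag in turn, and the other 12 lost it without tag 6-203 or, for CHPF and FAM53B, 4-1314 and 8-275, among other tags, with adjusted p of up to 0.194 (SPINT1 without tag 5-167). KIF20B and SREBF2 lost it without each of the 5 tags, and SPINT1 with no tag block (adjusted p = 0.0927). The ipsilateral libraries of this day held 29.2 ± 2.23 M reads and the contralateral ones 34.1 ± 2.12 M (exact permutation p = 0.0238, adjusted 0.0762). With log2 depth as a covariate 466 genes passed, and CEP162, KIF20B, FAM53B, CHPF, TOB2 and SPINT1 (adjusted p from 0.0508 to 0.106) and the extracellular matrix and macrophage lists (adjusted p = 0.6205 and 0.367) did not.

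On day 16, SYCP2 (1.32 ± 0.35), CEP162 (1.16 ± 0.26), HMGN5 (1.12), PPIG (1.00 ± 0.15), KIAA1551 (0.98), GCFC2 (0.97 ± 0.18) and LRP6 (0.43 ± 0.10) were higher in the ipsilateral horn. FAM53B (-0.50 ± 0.13), CHPF (-0.49 ± 0.11), PCDH1 (-0.40), GNA12 (-0.39), TRAPPC9 (-0.39) and EXT2 (-0.38) were lower. The extracellular matrix (adjusted p = 0.000349), secreted components (adjusted p = 0.0105) and epithelium (adjusted p = 0.0105, and 0.054 with no tag block) lists were lower as sets. In that order 0 of 36, 0 of 29 and 0 of 18 members were past the threshold over all genes and 0, 0 and 0 adjusted over the list alone. With an estimated correlation each stood at adjusted p = 0.952, and with the background covariate the extracellular matrix list and the secreted-components list, whose median turned to 0.027, did not pass (adjusted p = 0.0538 and 0.984). PGR (0.10 ± 0.24), ESR1 (-0.27 ± 0.18), OXTR (-0.38 ± 0.62), ISG15 (0.21 ± 1.15) and MX1 (-0.06 ± 0.91) did not pass.

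In total 674 genes passed on day 16, 614 higher (91.1%) and 60 lower, and DESeq2 called 1342, of which 65.4% were higher. Without tag 2-068, 5-137, 7-107 or 8-245 the count was 147, 326, 336 or 249. From the libraries of this day alone edgeR called 0 genes with the tag block (2993 at unadjusted p below 0.05) and 734 without it, and with the background covariate it called 0 (1436 at unadjusted p below 0.05). Of the 13 named genes that passed, PPIG and GCFC2 kept the call without each tag in turn, and the other 11 lost it without tag 2-068, among other tags, with adjusted p of up to 0.22 (SYCP2 without tag 2-068). SYCP2 did not pass with log2 depth as a covariate either (adjusted p = 0.0521), and with no tag block FAM53B, TRAPPC9 and LRP6 did not (adjusted p = 0.0505, 0.121 and 0.0744).

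The 4 days shared much of the horn difference. A total of 556 genes, 524 higher and 32 lower, passed on all 4 days in the same direction. LRP6 was among the genes named on each day. Across the 20356 genes, the log2 differences of pairs of days correlated with Spearman's rho between 0.463 (days 5 and 16) and 0.658 (days 7 and 13), where genes are not independent replicates. With the background covariate 0 genes passed on days 7, 13 and 16, so no gene passed on all 4 days. The libraries of day 16 alone with the tag block gave 0 calls too. The mean share of microRNA reads was higher in the ipsilateral horn on each day, by 1.18 to 1.31 times. Background reads therefore stay open as a source of part of this overlap. The test of whether the horn difference changed with the day called 0 genes with edgeR, 494 at unadjusted p below 0.05, 13 with DESeq2 and 0 with limma-voom. A higher count on day 5 than on day 16 is therefore not shown to be a difference between days. The 494 genes are 2.43% of those tested, where a share of 0.05 is expected with no change at any gene. The edgeR test may thus be too strict, and its 0 calls do not show that the horn difference was the same on all days.

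From day 5 to day 7, the endometrium lost most of its oxytocin receptor transcript. OXTR fell from 72.7 ± 18.9 to 9.51 ± 4.40 CPM (SD, n = 5 tags with horns summed, log2 fold change -2.93 ± 0.36, adjusted p = 5.27e-06). Here and in the later day comparisons, the 5 tags of a day may not be 5 separate animals. The progesterone receptor gene PGR fell from 16.2 ± 3.65 to 8.04 ± 1.32 CPM (-1.01 ± 0.17), and ESR1 from 23.1 ± 4.06 to 17.9 ± 2.25 CPM (-0.37 ± 0.12, adjusted p = 0.0235). The largest declines among the named genes included DMBT1 (-5.12 ± 1.01), a mucosal defence protein, the prostaglandin F receptor PTGFR (-4.60 ± 0.98), the calcium binding protein CALB1 (-3.97 ± 0.57) and SHISA2 (-3.95). Also falling were MSTN, which encodes myostatin (-3.47 ± 0.31; 17.1 ± 6.58 to 1.55 ± 0.582 CPM), MGAT5B (-3.27), TNS4 (-3.27), COL8A1 (-3.17) and AKAP4 (-3.06). Without tag 8-1350 of day 5 the values of PTGFR, AKAP4 and the actin gene ACTA2 were -2.24, -1.79 and -1.28, and without tag 4-184 that of DMBT1 was -3.42. SSLP1, an entry of the conceptus trophectoderm list that was not tested as a set, rose from 1.17 ± 0.317 to 31.1 ± 6.96 CPM (4.73 ± 0.24). Also rising were MYH7B (4.50), LY6G6E (4.22), the fatty acid transporter SLC27A6 (3.51), TMEM171 (3.41) and CES4A (3.33).

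The extracellular matrix list fell from day 5 to day 7, with 27 of 36 members lower and 1 higher (27 and 2 adjusted over the list alone; adjusted p = 7.21e-10, and 0.775 with an estimated correlation). COL12A1 (-2.47 ± 0.23), LOXL1 (-1.28), fibronectin FN1 (-1.27) and COL5A2 (-1.06) were among them. Markers of smooth muscle fell in 9 of 16 (11 adjusted over the list alone; adjusted p = 0.00258), for example TAGLN (-2.10), ACTA2 (-1.99) and CNN1 (-1.49), and markers of stroma fibroblasts in 10 of 14 (10 adjusted over the list alone; adjusted p = 0.00317), for example DPT (-2.07). Cell division genes fell in 12 of 40, with 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.000147), among them the replication genes MCM6 (-0.98), MCM4 (-0.69) and PCNA (-0.56). With an estimated correlation each of these 3 lists stood at adjusted p = 0.775. Interferon-stimulated genes rose in 9 of 39 and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.0328, and 0.8292 with an estimated correlation). Among them were HERC5 (1.13 ± 0.19), IRF7 (1.21), TRIM21 (0.68) and STAT2 (0.53). ISG15 (1.69 ± 0.87, adjusted p = 0.127) and MX1 (0.69 ± 0.61) did not pass.

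Single members of other lists also changed from day 5 to day 7. The triglyceride synthesis enzyme DGAT2 (3.14 ± 0.28) and the peptidase ANPEP (2.05) rose and CTGF (-1.76) fell, out of 5 higher and 2 lower among 14 progesterone-responsive genes (5 and 2 adjusted over the list alone). The transporters SLC1A1 (1.67) and SLC38A7 (1.57) rose, as did GATA2 (1.11), the aldose reductase AKR1B1 (1.73) and WNT11 (1.80). DKK3 (-1.20) and MYC (-1.78) fell. Within the epithelium list, CLDN7 (1.05) and SPINT2 (0.87) rose and KRT7 (-2.28) fell, out of 10 higher and 2 lower among 18 (10 and 2 adjusted over the list alone; adjusted p = 0.0765 for the set). In total 8397 of 20995 genes passed, 4282 higher and 4115 lower, and 1902 changed by 2-fold or more. From the contralateral libraries alone 3987 passed, and from the ipsilateral ones 5675. ESR1 lost its call without tag 1-315, 8-1350, 2-1337 or 2-371 (adjusted p = 0.0633, 0.096, 0.0607 and 0.0627), and the other 45 named genes that passed kept theirs.

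Between days 7 and 13 the endometrium began to express genes that had been nearly silent. IGFBP1 rose from 0.326 ± 0.312 to 234 ± 129 CPM (log2 fold change 9.46 ± 0.69, adjusted p = 5.87e-09) and CYP26A1, an enzyme that breaks down retinoic acid, from 0.652 ± 0.397 to 236 ± 45.8 CPM (8.49 ± 0.49), with 1.35 CPM in tag 2-371 of day 7 and 0.361 to 0.593 in the other 4. CALB1 (7.08 ± 0.59), the mucin MUC13 (6.51), the lysozyme LYZ1 (5.67), the protease MEP1B (5.39), the chloride channel CFTR (5.34 ± 0.34) and the zinc transporter SLC39A2 (5.31) rose as well. The uroplakin gene UPK1B fell from 211 ± 69.2 to 3.79 ± 2.18 CPM (-5.81 ± 1.09), alongside CDK5R2 (-8.12 ± 0.76), SERPINB12 (-6.90), WNT7A (-6.20 ± 0.81), LRG1 (-6.01), PLA2G3 (-5.41) and PTCHD2 (-5.38). PGR fell again, from 8.04 ± 1.32 to 3.75 ± 0.590 CPM (-1.10 ± 0.17), as did ESR1 to 11.9 ± 1.77 CPM (-0.60 ± 0.12) and OXTR to 3.32 ± 1.42 CPM (-1.52 ± 0.35).

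Cell division genes fell between days 7 and 13 in 36 of 40 members with a median log2 fold change of -2.21 (36 lower and 1 higher adjusted over the list alone; adjusted p = 1.64e-19, and 0.42 with an estimated correlation). Examples were UBE2C (-4.17 ± 0.36), BIRC5 (-3.41), PRC1 (-3.16) and NUSAP1 (-2.79). Progesterone-responsive genes rose in 10 of 14 and fell in 3 (10 and 3 adjusted over the list alone; adjusted p = 3.52e-05, and 0.196 with an estimated correlation). Among them were MSTN (3.79 ± 0.31), the glucose transporter SLC5A1 (3.04) and the retinol binding protein RBP4 (1.43). Secreted components rose in 15 of 29 and fell in 6 (16 and 6 adjusted over the list alone; adjusted p = 0.00165, and 0.662 with an estimated correlation). Among them were the protease inhibitors CST6 (3.32) and TIMP2 (1.97). Immediate early genes rose in 13 of 27 and fell in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.00223, and 0.89 with an estimated correlation). Among them were IER3 (1.56), PPP1R15A (0.99) and KLF6 (0.96).

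Heat shock and unfolded protein response genes fell in 14 of 26 and rose in 2 (15 and 3 adjusted over the list alone; adjusted p = 0.00055, and 0.706 with an estimated correlation). Among them were CRELD2 (-1.39), MANF (-0.99), PDIA6 (-0.71) and the endoplasmic reticulum chaperone HSPA5 (-0.70). Ciliated epithelium markers fell in 13 of 24 and rose in 0 (14 and 0 adjusted over the list alone; adjusted p = 0.0204, and 0.989 with an estimated correlation). They included MCIDAS (from 0.416 to 0.00327 CPM) and CCNO (-4.91), which direct the formation of multiple cilia, and TPPP3 (-0.98). Blood vessel endothelium markers rose in 8 of 14 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.0399, and 0.989 with an estimated correlation). They included KDR (0.83), EMCN (0.65) and ERG (0.63). Among other list members, the inositol and glucose transporter SLC5A11 (4.16), the prostaglandin synthase PTGS2 (4.04 ± 0.34) and PLA2G4A (1.30) rose. GATA2 (-1.16), GREB1 (-1.53) and the sodium channel subunit SCNN1A (-2.59) fell. ISG15 (-1.51 ± 0.86) and MX1 (-0.52 ± 0.61) did not pass. In total 9346 genes passed, 4539 higher and 4807 lower, and 2561 changed by 2-fold or more. The 46 named genes that passed kept the call without each tag in turn, although a tag that joins 2 heifers leaves both in through other sums. In single horns, 5641 genes passed from the ipsilateral libraries alone and 6550 from the contralateral ones.

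From day 13 to day 16, OXTR rose from 3.32 ± 1.42 to 19.3 ± 5.09 CPM (log2 fold change 2.54 ± 0.36, adjusted p = 0.000442). CRYGS, a crystallin gene of the progesterone-responsive list, rose from 0.865 ± 0.529 to 15.5 ± 6.37 CPM (4.16 ± 0.41). So did the vitamin D degrading enzyme CYP24A1 (2.94 ± 0.42), carbonic anhydrase CA2 (2.26), CYP1A1 (2.01), the laminin LAMA3 (1.76), HSPA6 (1.69), SLC26A7 (1.60), the potassium channel KCNJ15 (1.78) and the glucose transporter SLC2A1 (0.99). TDGF1 fell from 1242 ± 174 to 167 ± 132 CPM (-2.90 ± 0.42), with 398 CPM in the sum of tag 5-137 and 84.0 to 141 CPM in the other 4. COL22A1 (-3.36 ± 0.40), FAM135B (-3.15), ADCYAP1R1 (-2.68), CES4A (-2.68), CYP26A1 (-2.44 ± 0.36), DGAT2 (-2.10 ± 0.27), the lipoprotein lipase LPL (-1.59) and CCNB1 (-1.04) fell as well. PGR went from 3.75 ± 0.590 to 5.54 ± 1.17 CPM (0.56 ± 0.17, adjusted p = 0.0528), which did not pass, and ESR1 (-0.12 ± 0.12; 9.18 CPM in tag 3-155 of day 16, 10.9 to 11.6 in the other 4), ISG15 (-2.29 ± 0.90, adjusted p = 0.14) and MX1 (-1.30 ± 0.62) did not pass either.

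Interferon-stimulated genes were lower as a set on day 16 than on day 13, with a median of -0.92 (adjusted p = 9.19e-10, and 0.761 with an estimated correlation). Over all genes 2 of 39 members passed (2 adjusted over the list alone), HERC5 (-0.90 ± 0.19) and XAF1 (-1.01 ± 0.28). Heat shock and unfolded protein response genes rose in 7 of 26 and fell in 0 (12 and 0 adjusted over the list alone; adjusted p = 2.37e-05), among them DNAJB1 (0.52), HSPB1 (0.45), PDIA4 (0.29) and HSPA5 (0.27). Cholesterol genes rose in 4 of 23 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 2.4e-05), namely INSIG1 (0.87 ± 0.15), HMGCS1 (0.66), MVD (0.55) and ACAT2 (0.46). With an estimated correlation both of these lists stood at adjusted p = 0.761. Ciliated epithelium markers were higher as a set (median 0.53, adjusted p = 2.4e-05, and 0.842 with an estimated correlation). Over all genes 1 of 24 passed (1 adjusted over the list alone), CFAP126 (0.31 ± 0.09).

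In total 1349 of 20995 genes passed from day 13 to day 16, 536 higher and 813 lower, and DESeq2 called 2197. Without tag 5-140 of day 13, or 2-068 or 3-155 of day 16, the count was 834, 865 or 824. In single horns, 88 genes passed from the ipsilateral libraries alone (180 without library 5-137) and 328 from the contralateral ones. Of the 30 named genes that passed, 23 kept the call without each tag in turn, and the others lost it without at least 1 tag. Their highest adjusted p was 0.0879 for HSPA6 (without 7-107), 0.083 for XAF1 (without 4-1314), 0.0626 for HSPB1 (without 5-140), and 0.0513, 0.0813, 0.0922 and 0.0807 for ACAT2, MVD, HMGCS1 and CFAP126 (each without 3-155).

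**Figure D4:**
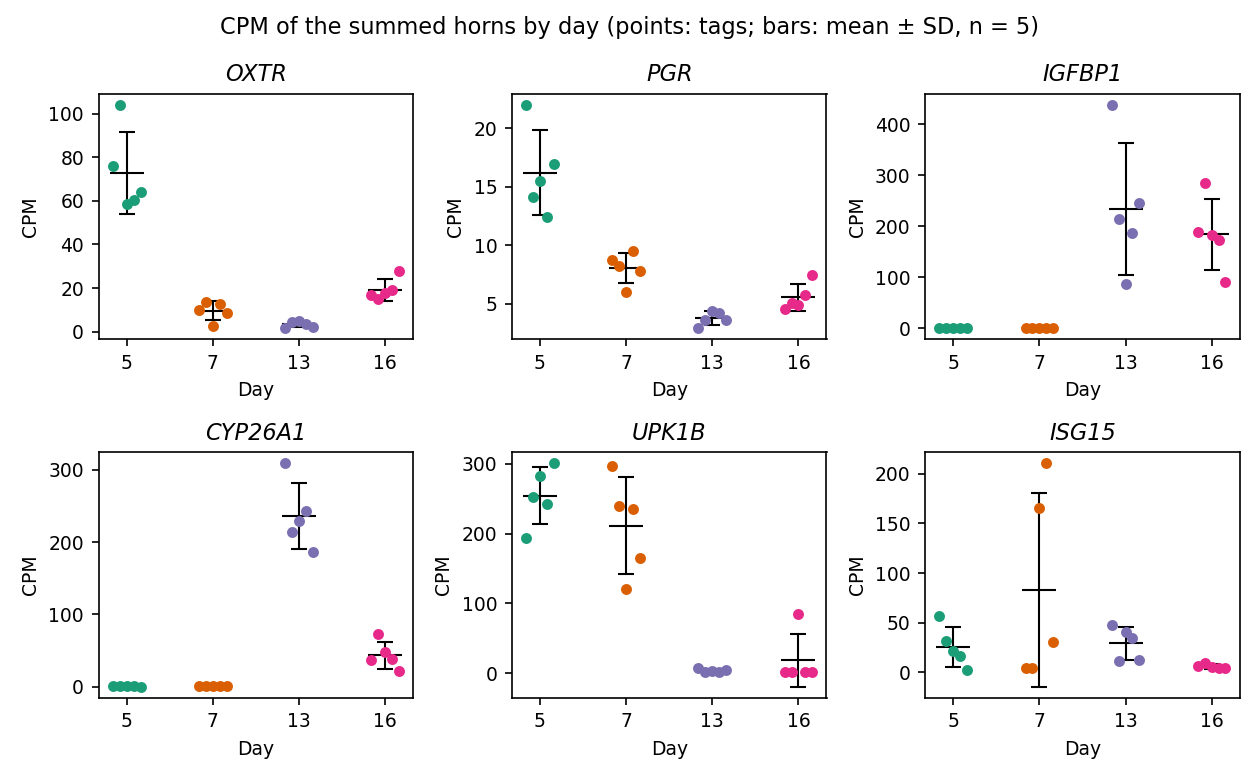
CPM of the 2 horns summed per tag (vertical axis) by day for OXTR, PGR, IGFBP1, CYP26A1, UPK1B and ISG15, with 1 point per tag and bars for the mean ± SD of 5. OXTR was at 72.7 CPM on day 5, 3.32 on day 13 and 19.3 on day 16, and the single high UPK1B point of day 16 (85.5 CPM) is tag 5-137.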

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

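The background and depth covariates, the tests of epithelium share, of the tags and of library 5-137, and the comparison of the horn difference between days over the lists, were chosen after the result was seen. The depth covariate replaced a first test of depth, the correlation of days 5 and 13 across genes (Spearman's rho = 0.564), which was dropped because the ipsilateral horn had the lower median depth on both days.

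The horn differences were shared by the 4 days and small. Depth as the whole cause is argued against: although 65.0% of the called genes followed depth within groups against the direction of their horn difference, 100.1% of the median difference of the 7570 genes was left with log2 depth as a covariate and 7112 kept the call and direction, but on day 13 the count went from 890 to 466. A lower share of epithelium that raised the other cell types alike is argued against for the average. Of the 16 called members of the other cell type lists, 37.5% were higher in the ipsilateral horn (6 higher, 10 lower). The members are few and a gain of only some cell types is possible, so a lower share of epithelium itself stays open. On day 5 it stays open as well, where 66.7% were higher and the called members were too few to decide (4 higher, 2 lower). More background reads in the ipsilateral libraries stay open and may account for part: 73.4% of 7552 called genes followed the microRNA and tRNA share within groups in the direction of their horn difference, which 4.3% of 1000 shuffles of the share within groups reached. With that share as a covariate the median difference went from 0.29 to 0.20 and the standard error from 0.06 to 0.13, so most calls ended with smaller differences and wider errors, and 283 genes passed; a biological difference of the horns stays open too, and GC content and length were not tested.

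The tags paired the libraries of the horns in few cases. Too few genes to tell heifers apart is argued against, since the second best match was equal at no more than 84.6% of the 13 on/off genes. Tags of 1 horn assigned to other heifers of the day stay open as a candidate explanation: 5 of 20 tags matched their own tag best, 4 are expected with tags shuffled within days, and 0.372 of 1e+05 shuffles gave as many. The values go with this explanation. By the correlation of deviations, 20 of 20 best matches were mutual, and the on/off genes picked the same partner in all 20 cases. Which horn would carry the wrong tags was not tested. No biological explanation was tested.

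Ipsilateral day 16 library 5-137 lay at 6.91 on the first principal component (the others at 50.3 to 56.8), with 33 genes of the early days at a median 0.324 of their day 7 level against 0.028 to 0.047 in the other day 16 libraries. A whole library of day 5 or 7 under this label is argued against, since 20 genes high only on days 13 and 16 were at a median 0.63 of the other day 16 libraries. A mixture with 18 of the 20 libraries of days 5 and 7 is argued against, as 0 of them had their on/off genes at the level a mixture needs, taken as 0.5 of the expected level. This rests on few genes. Only 3 on/off genes were off in the matched library, contralateral 7-107, and 1 to 3 of them were on in each of the 18, often only 1. LOC787803 among them was not silent there, at 2.74 CPM. For 2 day 5 libraries, ipsilateral 4-184 and contralateral 7-300, the 13 on/off genes cannot decide on a mixture. None of the 3 on/off genes off in the matched library was on in these 2. In 2 of the 4 rule versions tried these 2 were at the level needed, and the version with 23 genes left 0 of 20 libraries. In the other versions genes off in the matched library were above every library called off, which goes with a mixture: LOC100848475 at 2.56 CPM (others at most 0.249) and, with 23 genes, also LRG1 at 10.8, TNS4 at 5.91 and CLDN22 at 1.55, all 4 called between days, and a true difference of that heifer stays open too, untested.

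Other samples stood apart from their group of 5, in 6 of 84 groups tested where 4.2 are expected by chance. Contralateral day 13 library 4-1314 lay at 48.3 on the first component, with the others at 37.1 to 38.2. In the summed horns, tag 2-371 of day 7 had 1.35 CPM of CYP26A1 (the others 0.361 to 0.593), tag 3-155 of day 16 had 9.18 CPM of ESR1 (the others 10.9 to 11.6), and tag 5-137 had 398 CPM of TDGF1 (84.0 to 141) and 85.5 CPM of UPK1B (0.968 to 1.90).

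The horn difference of whole lists differed between days in 21 of 174 tests of the preset camera correlation, and in 0 with an estimated correlation (smallest adjusted p = 0.477). As median changes of the log2 horn difference, day 7 minus day 5 gave 0.37 for cell division, -0.15 for WNT signalling, 0.17 for cholesterol synthesis and uptake, 0.36 for epithelium, 0.52 for ciliated epithelium, -0.21 for stroma fibroblasts, -0.39 for smooth muscle and -0.66 for Schwann cells and nerve. Day 13 minus day 5 gave 0.38 for cell division, 0.28 for epithelium, 0.48 for ciliated epithelium and -0.34 for smooth muscle. Day 16 minus day 5 gave 0.63 for cell division, 0.27 for cholesterol, 0.41 for epithelium and -0.48 for smooth muscle. Day 16 minus day 7 gave -0.089 for steroid hormone receptors, 0.22 for cell division and 0.10 for heat shock, and day 16 minus day 13 gave 0.13 for cholesterol and 0.56 for mast cells.

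The mitochondrial genome row, which entered no gene test, took a mean of 0.424% of the reads on day 13. Its share was at 1.01, 1.21, 1.37 and 1.12 times the contralateral one in the ipsilateral horn on days 5, 7, 13 and 16 (exact two-sided permutation p = 0.984, 0.421, 0.0714 and 0.111, adjusted over 16 tests 0.984, 0.518, 0.141 and 0.162), which did not pass.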

How the results depend on the processing

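Tests chosen after the results were seen were the background and depth covariates, the fits of 1 day with no block and the fits without ipsilateral day 16 library 5-137. Both covariates were fitted in the horn comparisons alone, so whether the calls between days depend on the background share was not tested. In the fit of all 40 libraries the replicate block changed no count by over 1.5 times: with no replicate block 4628, 2386, 1165, 922 and 7768 genes passed for days 5, 7, 13, 16 and the average. Nor did the libraries of 1 day with no replicate block, where 2884, 1624, 742 and 734 passed. Counts that moved by over 1.5 times were as follows, and the cause was not tested except where fewer libraries entered the fit. With the background covariate 600 genes passed on day 5, 0, 0 and 0 on days 7, 13 and 16 (edgeR, 1673, 1290 and 1436 at unadjusted p below 0.05) and 283 for the average. With the depth covariate 466 passed on day 13. From the libraries of the day alone with the replicate block 1760, 619, 388 and 0 passed on days 5, 7, 13 and 16 (edgeR, 2993 at unadjusted p below 0.05 on day 16). DESeq2 called 1720 on day 13, 1342 on day 16, 13 for the change with day and 2197 from day 13 to 16. In single horns, 3987 genes passed from day 5 to 7 (contralateral), 5641 from day 7 to 13 (ipsilateral, 5526 without library 5-137), and 88 (ipsilateral, 180 without 5-137) and 328 (contralateral) from day 13 to 16. Of the 18 list calls between horns, 0 held with camera at an estimated correlation, 4 with fry and 16 with no replicate block, and of the 16 between days 0 held at an estimated correlation and 10 with fry. Including lists without a call in camera, fry called 8 between horns (2 higher, 6 lower) and 23 between days.

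With 1 tag left out in turn, the counts ranged from 2950 to 4040 (day 5), 839 to 2301 (day 7), 349 to 893 (day 13), 147 to 793 (day 16), 6925 to 7997 (average), 0 to 0 (change with day), 7113 to 8676 (day 5 to 7), 8426 to 9393 (day 7 to 13) and 824 to 1347 (day 13 to 16). The lowest counts came without 2-1337 on day 7, 6-203 on day 13, 2-068 on day 16 and day 16 3-155 from day 13 to 16. Of 245 values of named genes, 240 kept direction and side of the threshold with DESeq2, 229 with limma-voom, 240 with no filter, 244 with RLE scaling and 245 with a robust prior. Of 115 horn values, 101 did with no replicate block, 26 with the background covariate (78 kept the direction and lost the call) and 101 with the depth covariate (10 lost the call). In the fits of 1 day with no block 72 of 91 did and 15 lost the call. The 115 horn values include those of PGR, ESR1, OXTR, ISG15 and MX1, which passed in no horn comparison. Fewer than 26 calls of named genes therefore held with the background covariate. Every named call of days 7, 13 and 16 was lost with it, since 0 genes passed there. With the background covariate TNXB on average was at 0.096, not past the threshold, and the secreted-components list at 0.14 (day 7), 0.060 (day 13) and 0.047 (average). Of the 18 list calls between horns 9 held with it and the other 9 were lost, among them the secreted-components list of day 16, whose median was at 0.027. The other values that changed sign belong to MX1, PGR, ESR1, OXTR and ISG15, in comparisons where they had not passed. With limma-voom, the log2 values were MX1 0.14 (days 7 to 13), ISG15 0.045 (day 5), 0.11 (day 7), 0.017 (day 13) and 0.093 (the average), OXTR 0.019 (day 13) and 0.0066 (the average). With no replicate block, the log2 values were ISG15 0.29 (day 5), 0.013 (day 13) and 0.056 (the average), MX1 0.046 (day 5), OXTR 0.053 (day 13) and 0.031 (the average). With the background covariate, the log2 values were PGR -0.0069 (day 5), -0.038 (day 13), -0.037 (day 16) and -0.018 (the average), OXTR -1.46 (day 5) and -1.68 (day 7), ISG15 0.14 (day 13), MX1 0.12 (day 13), 0.15 (day 16) and 0.033 (the average). With the depth covariate, the log2 values were ISG15 0.34 (day 5), MX1 0.099 (day 5), OXTR 0.32 (day 13) and 0.058 (the average). With no replicate block in the libraries of 1 day, the log2 values were ISG15 0.35 (day 5) and 0.0081 (day 13), MX1 0.10 (day 5), OXTR 0.047 (day 13). With no replicate block and without ipsilateral day 16 library 5-137, the log2 values were PGR -0.025 (day 16), MX1 0.016 (day 16), ISG15 0.075 (the average). With 1 tag left out in turn, days 7 to 13 ranged from -0.80 to 0.084 for MX1. For day 5 it was -0.25 to 0.083 for ESR1, -0.30 to 0.56 for OXTR, -1.59 to 1.16 for ISG15, -1.31 to 0.74 for MX1. For day 7 it was -0.13 to 0.048 for ESR1, -0.48 to 0.52 for OXTR, -1.93 to 0.30 for ISG15, -1.30 to 0.41 for MX1. For day 13 it was -0.018 to 0.28 for PGR, -0.62 to 0.57 for OXTR, -0.69 to 0.51 for ISG15, -0.68 to 0.29 for MX1. For day 16 it was -0.072 to 0.26 for PGR, -0.80 to 0.082 for OXTR, -0.035 to 0.45 for ISG15, -0.27 to 0.21 for MX1. For the average it was -0.19 to 0.11 for OXTR, -0.57 to 0.12 for ISG15, -0.49 to 0.026 for MX1. At the depth and number of libraries of day 5 the simulated horn comparison found 23.9% of 1.5-fold changes, and how much of this limit comes from depth was not tested. With few genes changed and no animal differences simulated, that share does not describe the real fit.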

Other observations

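Tests of other splits of the samples were planned, and none in this part was chosen after the result was seen. Several lists that did not pass as sets held members that moved between days. From day 5 to day 7, 11 of 27 immediate early genes fell and 2 rose (11 and 2 adjusted over the list alone, set adjusted p = 0.11), 12 of 36 WNT signalling genes fell and 4 rose (12 and 4, set adjusted p = 0.107), and 10 of 24 genes of water channels and ion transport fell and 4 rose (10 and 4, set adjusted p = 0.202). Of 24 ciliated epithelium markers, 10 rose and 2 fell (13 and 2, set adjusted p = 0.107). Neutrophil markers fell in 5 of 7 (5, set adjusted p = 0.177) and steroid hormone receptors and cofactors in 8 of 16, with 5 higher (9 and 5, set adjusted p = 0.679). From day 7 to day 13, glucose and amino acid transporters rose in 11 of 28 and fell in 9 (11 and 9, set adjusted p = 0.692).

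Lists that passed in no main horn or day comparison had lowest adjusted p there of 0.107 (WNT signalling), 0.161 (MHC class II), 0.177 (neutrophils), 0.202 (water channels and mast cells), 0.22 (lymphatic endothelium), 0.231 (transporters and oviduct epithelium), 0.295 (B and plasma cells, T and NK cells, red blood cells), 0.309 (prostaglandin and oxytocin pathway), 0.401 (steroid hormone receptors), 0.468 (Schwann cells and nerve) and 0.557 (gland epithelium). In the tests of the horn difference between days, flagged above, WNT signalling, mast cells, steroid hormone receptors and Schwann cells and nerve did pass at the preset correlation.

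Other splits of the samples were examined with 100 splits of the same samples, the real one included, fitted without the block, for a single day or pair of days on its libraries or sums alone and for the average on all 40 libraries. For the gene counts of days 5, 7, 13 and 16 and of the average, 1 split, the real one, reached the real count (2884, 1624, 742, 734 and 7768 genes, highest of the others 309, 8, 24, 6 and 10). The same holds from day 5 to 7, 7 to 13 and 13 to 16 (7635, 8516 and 1238 genes, highest of the others 3, 913 and 251). Each split drew on the real samples, so a split that mixed the days or horns carried their difference as spread within its sides. How far this lowered the gene counts of the other splits was not tested. For the change with day all 100 splits reached the real count of 0 edgeR calls (494 at unadjusted p below 0.05 with the block), and the highest other split called 299. In the horn comparisons the splits did not keep apart the pairs of libraries that matched at the on/off genes, which the real groups always part, and splits that part them were not run. Between days, the splits did not keep together sums that may share a heifer. Apart from the change with day, the real gene counts were above those of every other split. With these limits, the splits do not exclude chance for them. For the numbers of lists the splits cannot decide. A split with unequal numbers of a horn or day on its sides kept part of the real difference, so it is no measure of chance alone. On days 5, 7, 13 and 16 and on average 95, 91, 64, 98 and 94 splits called as many as the real 5, 4, 7, 3 and 4 lists (highest of the others 18, 14, 15, 13 and 18). From day 5 to 7, 7 to 13 and 13 to 16, 99, 61 and 84 splits called as many as the real 4, 7 and 4 lists (highest of the others 18, 15 and 13). These counts of lists neither exclude chance nor point to it as the cause.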
